A study of Homo sapiens with 9 samples.

How the data were processed

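Per the labels, A375 cells expressing Cas9 were transduced with the Brunello library at a multiplicity of infection below 0.3 and selected with puromycin at 0.75 µg/mL from day 2. Cells were collected on day 6 and day 10, and on day 10 fixed and stained cells were sorted into CD58-low and CD58-mid populations. Guides were amplified from up to 10 µg of genomic DNA per reaction over 28 PCR cycles and sequenced. The deposited tables hold 52 columns for 9 samples: 4 columns for the virus, day 6 and day 10 samples, and 8 for each sorted sample, as 4 columns for each of technical replicates A and B. The first deposited table gives counts, the number of reads per guide. The second deposited table gives the authors' normalized values, a signal in no named unit. Checked against the counts, it is the count times 1 factor per column (0.635 to 1.551), so the authors scaled each column and nothing else. The submitters' processing notes name MAGeCK 0.5.9.2; its settings and the read trimming and mapping are not given in the sources used here.

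The fixed parts of the design were chosen before the data were examined: the comparisons, the tests, the filter, the gene lists, the rule for named genes and the alternative settings, except where a passage says that something was chosen after values were seen. Reads of all columns of a sample were summed, so that each biological replicate counts once. Pairs of columns within a library differed by little more than counting error, with a chi-squared per degree of freedom of 1.0 to 1.032. Technical replicates A and B differed by more, at 31.6 and 36.0 in CD58-low and 6.36 and 6.39 in CD58-mid. Total reads per sample ran from 8635479 to 25357120, with a median of 96 to 277 reads per guide. Intervals and limits for 0 reads, taken as 3 reads of the total, cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

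Guides with at least 10 reads in at least 2 of the 9 samples were kept (76005 kept, 436 removed). Counts were scaled with TMM factors and fitted in edgeR 4.0.16 (R 4.3.3) with a robust quasi-likelihood model of 5 groups, which leaves 4 residual degrees of freedom, and 6 comparisons were tested from that single fit. Genes with at least 2 guides left, 19113 in all, were tested by alpha-RRA on the one-sided guide p ranks, where guides in the top 25% count. The null came from 5000000 sets of the same size of independent uniform random ranks, so the smallest p is 2e-07. Dependence between the guides of a gene is not part of this null. P values were adjusted by Benjamini-Hochberg over genes, separately for each direction, with a threshold of 0.05. The value of a gene is the median log2 fold change of its guides from the fit with its SD over guides, and its summed CPM as mean ± SD over the 2 replicates. Comparisons that share libraries share their chance deviations.

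The replicate numbers of the day 6, day 10 and sorted samples are shared in the labels, and sorted cells came from the same cultures. Across guides the replicate differences of pairs of groups correlated at 0.073 to 0.234. The main fit had group only, as fixed at the start, and the fit with the replicate number as a block is given beside a result where it moved it by more than 1.5 times.

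The named genes follow a rule fixed before the files were opened. CD58, CMTM6 and CD274 are always given. For CD58-low against CD58-mid the rule takes the first 15 enriched and first 10 depleted genes by p with the same sign in both replicates, filled up with genes that did not pass where fewer than 10 did. For the comparisons with day 10 it takes the same genes and the first 3 per direction, and for growth the 10 genes with the lowest and the 10 with the highest fold against the virus, with 5 and 5 at the other times. From each list it takes up to 4 passing members. A few genes that the rule names are not reported here. Further members named as added when adjusted over the list alone, the 3 further genes of CD58-mid against day 10 and the genes of the opening of the other observations were chosen after their values were seen. Lists were tested on their guides with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry (limma 3.58.1), adjusted over the lists of a comparison. At the preset correlation the camera p rests on the number of guides and does not measure the spread between libraries of a group. There were 19 lists for the sort and 8 for growth.

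Alternative settings were DESeq2 size factors and the DESeq2 1.42.0 Wald test, limma on the deposited normalized values, no filter and a stricter filter of 100 reads, the replicate block, a fit of only the groups compared, fry per gene, the top 10% of guides in RRA, each technical replicate alone, and leaving out each library. In the limma alternative the normalized values were averaged over the columns of a sample in place of the planned sum, since sorted samples have more columns, and log2(value + 1) was taken. This change and limma voom with group weights were chosen after seeing the data. Scaling and a null from non-targeting guides were planned but not run, because the tables name no such guides.

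The scripts were tested on simulated negative binomial counts, with 1 dispersion per group for all its guides (0.352 in CD58-low), and with 50 genes changed for each fold and direction. The changed genes were drawn from those with 4 guides, leaving out the genes of lowest abundance. All 4 guides of a changed gene had the same fold. Recovery of real genes whose guides differ in effect may therefore be lower in both simulated comparisons. For CD58-low against CD58-mid the test recovered 90% of genes raised 4-fold, 18% raised 2-fold, 68% lowered 4-fold and 2% lowered 2-fold, and 3 of 92 calls were false. The draw did not model loss of guides, and 2.52% and 5.02% of guides had no reads in the real CD58-low libraries. Recovery of lowered genes and the share of false calls may therefore differ in the real sort. For day 10 against day 6 it recovered 96% to 100% of each kind, and 9 of 206 calls were false. Chromosomes were taken from the RefSeq annotation of the human genome by gene symbol (17851 symbols matched directly and 1135 by a synonym). Tables and figures were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. No guide sequences or genome came with the tables, so cutting sites were not examined.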

Results

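The screen measured how often each guide RNA of a genome-wide knockout library was found in Cas9-expressing A375 cells, a human melanoma line, and in populations sorted from them by the amount of CD58 on the surface. CD58 is the ligand of CD2 on T cells and natural killer cells, and it occurs in a transmembrane form and in a form held by a glycosylphosphatidylinositol (GPI) anchor. The table counts 76441 guides against 19114 genes, 19107 of which have 4 guides. There were 9 samples in 5 groups: the library virus (1 sample), cells on day 6 (2), unsorted cells on day 10 (2), and the CD58-low (2) and CD58-mid (2) populations, sorted on day 10 after formaldehyde fixation and staining. Total reads were 16227221 for the virus, 12294406 and 9504934 on day 6, and 12837012 and 8635479 on day 10. The CD58-low libraries held 25357120 and 16195790 reads and the CD58-mid libraries 24454715 and 18835903. Guides with 0 reads numbered 152 in the virus, 378 and 452 on day 10, 420 and 496 in CD58-mid, and 1929 and 3836 in CD58-low. Pearson's correlation of log2 CPM between the 2 replicates, across guides, which are not independent replicates, was 0.907 on day 6, 0.928 on day 10, 0.918 in CD58-mid and 0.712 in CD58-low. The edgeR dispersion of the CD58-low group was 0.352, against 0.0454 in CD58-mid and 0.028 on day 10, so every comparison with CD58-low rests on libraries that varied more than the rest.

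The comparison of CD58-low with CD58-mid asks which knockouts are over-represented among cells with little CD58 on the surface. Guides against CD58 itself rose most, with a median log2 fold change of 6.91 (SD over its 4 guides 0.38), and their summed abundance was 391 ± 17.3 CPM in CD58-low and 3.12 ± 1.79 CPM in CD58-mid (mean ± SD, n = 2), a 125-fold difference. DNAJC13, a J-domain protein of early endosomes, was next, at 285 ± 6.68 against 21.2 ± 2.75 CPM (log2 fold change 3.63). PGAP2, which acts on the lipid of GPI-anchored proteins after attachment, followed at 491 ± 40.4 against 72.1 ± 7.75 CPM (log2 fold change 2.91). CUL3, the scaffold of a family of ubiquitin ligases, reached 651 ± 101 CPM in CD58-low and 120.1 ± 3.84 CPM in CD58-mid (log2 fold change 2.38). CMTM6, a membrane protein known to stabilise PD-L1, was enriched with a log2 fold change of 2.07 (SD over guides 0.57), at 131 ± 29.3 against 31.8 ± 2.17 CPM. Guides against CD274, the gene of PD-L1, did not pass: they stood at 50.1 ± 10.3 CPM in CD58-low and 59.1 ± 2.81 CPM in CD58-mid.

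In all, 60 of 19113 genes tested were enriched in CD58-low and 1 was depleted. The threshold was an adjusted p of 0.05 or less in the robust rank aggregation (RRA) of edgeR guide p values. The 20 genes at the smallest p that 5000000 sets of random ranks allow, 2e-07, share an adjusted p of 0.000191. They include the genes above that passed and the further genes named here from the first 15. NF2, the merlin tumour suppressor upstream of Hippo signalling, had a log2 fold change of 1.83, at 225 ± 57.4 against 66.7 ± 12.2 CPM. KMT2D, a histone methyltransferase, rose by 1.71 on the log2 scale (250.3 ± 51.3 against 69.4 ± 8.41 CPM), and the kinase DYRK1A by 1.69 (242 ± 10.8 against 74.95 ± 2.53 CPM). The transcription factor RUNX1 rose by 1.55 (249 ± 5.19 against 76.5 ± 11.6 CPM) and the HMG-box protein TOX4 by 1.49 (99.7 ± 0.21 against 36.9 ± 1.42 CPM). The remaining 5 of the first 15 belong to the GPI pathway: PIGV, PIGW, PIGX, PIGO and PIGP. All 60 genes had a higher median guide abundance in CD58-low in both replicates.

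**Figure D1:**
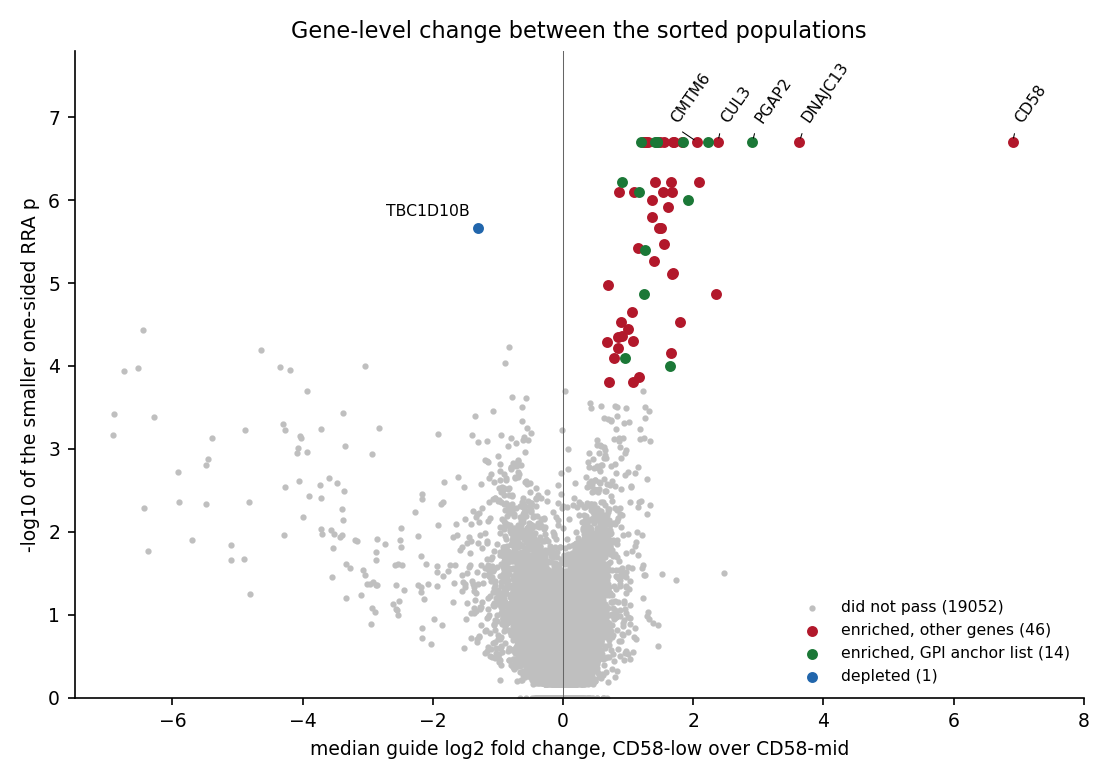
Gene-level comparison of CD58-low with CD58-mid: the x axis is the median log2 fold change of a gene's guides, the y axis the negative log10 of the smaller one-sided RRA p, and each point is 1 of 19113 genes. The 60 enriched genes (14 of them from the GPI anchor list) and the 1 depleted gene are coloured, and CD58 lies farthest to the right at 6.91. The top line of points is the smallest p the random null allows, 2e-07.

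**Figure D2:**
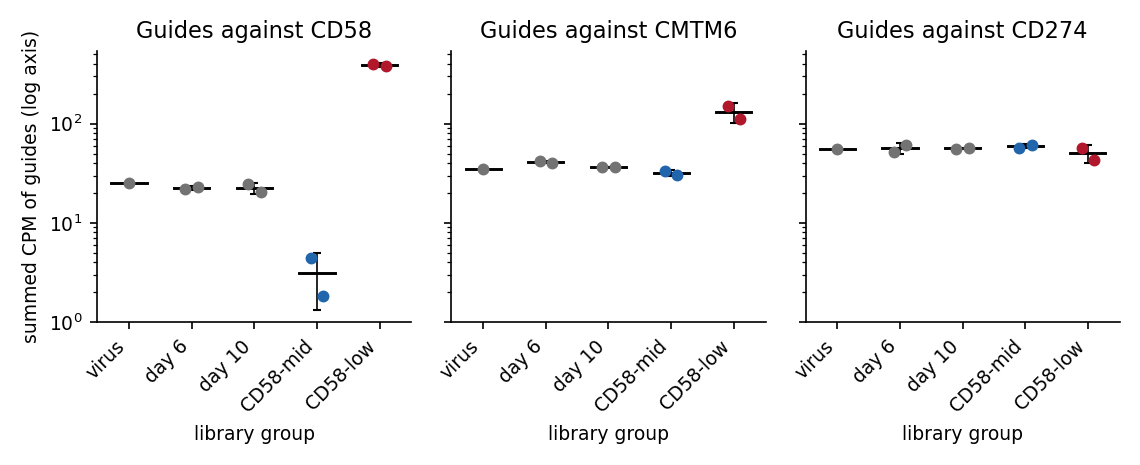
Summed abundance of the 4 guides against CD58, CMTM6 and CD274 in every library, in CPM on a log axis; points are libraries, horizontal bars group means and error bars SD (n = 2, virus n = 1). CD58 guides stood at 391 CPM in CD58-low, 3.12 CPM in CD58-mid and 22.4 CPM on day 10, and CD274 guides at 50.1 CPM in CD58-low and 59.1 CPM in CD58-mid.

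Genes of GPI anchor synthesis and attachment formed the clearest group among the 19 lists tested. Of the 32 measured members 14 were enriched and none was depleted, the other 18 did not pass, and 17 were enriched when adjusted over the list alone, which adds PGAP3, PIGM and PIGQ. The median log2 fold change over the list was 0.89. PIGV, a mannosyltransferase, was at 191 ± 26.3 CPM in CD58-low and 43.5 ± 7.63 CPM in CD58-mid (log2 fold change 2.23). PIGW, which acylates the inositol, had a log2 fold change of 1.84 (99.3 ± 30.5 against 32.5 ± 0.64 CPM). PIGX, a partner of the mannosyltransferase PIGM, had 1.44 (154 ± 20.3 against 63.1 ± 1.59 CPM). The other passing members were PIGA, PIGB, PIGC, PIGF, PIGH, PIGL, PIGN, PIGO and PIGP, PGAP2, and DPM1 of the enzyme that makes the mannose donor. None of the 5 transamidase subunits, which attach the finished anchor, passed, and their mean log2 fold change was 0.08 (SD 0.27); the split by step was made after the values were seen. The camera test of the list gave an adjusted p of 1.4e-49, and with an estimated correlation the adjusted p was 0.000847. The 14 enriched genes became 9 without CD58-low replicate 1, where DPM1, PIGA, PIGB, PIGF and PIGN did not pass, 7 with technical replicate B alone and 3 with fry per gene (PGAP2, PIGF and PIGO). PIGN also did not pass with any 1 of the other 3 sorted libraries left out. The same holds for PIGC and PIGW with CD58-low replicate 2 left out, PIGF with either CD58-mid library left out, and PIGA with CD58-mid replicate 2 left out. With the replicate number as a block PIGF did not pass (adjusted p 0.0554) and PIGQ did (0.0207).

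**Figure D3:**
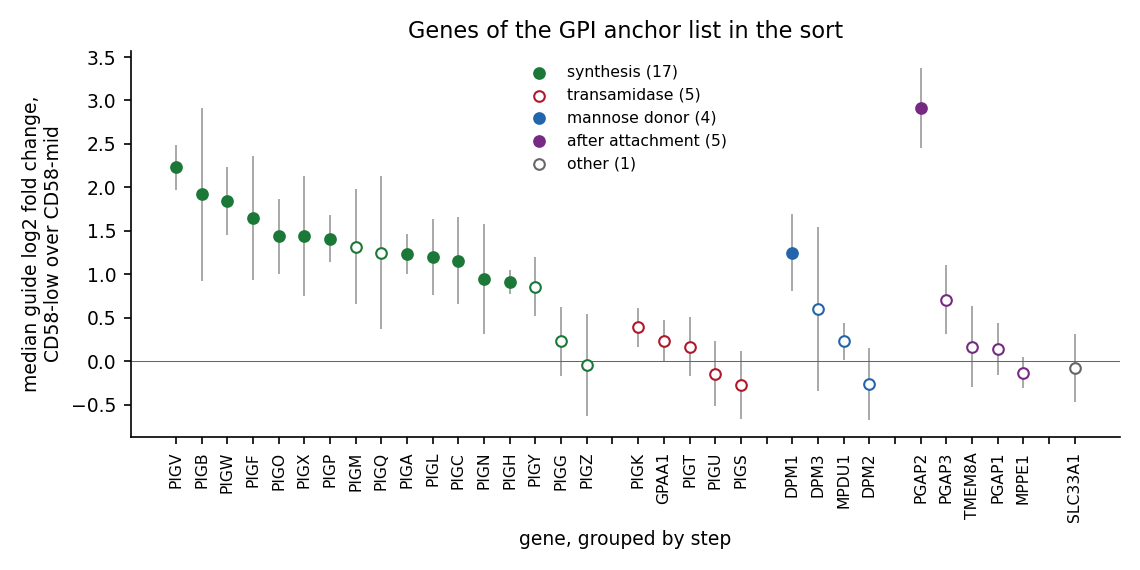
Median log2 fold change of guides in CD58-low over CD58-mid (y axis) for each of the 32 genes of the GPI anchor list (x axis), grouped by step; error bars are the SD over a gene's guides, filled points passed the gene-level test and open points did not. Of 17 synthesis genes 12 passed, and the 5 transamidase genes lie between -0.27 and 0.39.

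The list of N-glycan synthesis, transfer and trimming moved the other way as a set, with a median log2 fold change of -0.14 over 62 genes (camera adjusted p 0.00881; adjusted p 0.0336 with an estimated correlation). No single member passed over all genes by RRA, and 4 were depleted when adjusted over the list alone. These were MPI, which makes mannose-6-phosphate, at 35.5 ± 4.34 CPM in CD58-low against 63.0 ± 0.33 CPM in CD58-mid, the mannosyltransferases ALG12 (log2 fold change -1.0) and ALG9 (-0.84, from -1.29 with technical replicate A alone to -0.54 with B alone), and STT3A (-0.69), a catalytic subunit of oligosaccharyltransferase. In the CMTM and CKLF family CMTM6 alone of 9 members passed, and adjusted over the list alone CMTM8 (log2 fold change 0.61) also did (adjusted p 0.0471), with log2 fold changes from 0.02 without CD58-low replicate 2 to 1.02 without CD58-low replicate 1. That family was not called by camera (adjusted p 0.0727); its median log2 fold change was -0.14 while its mean was 0.17.

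The other 16 sort lists were not called by camera as sets, but several held genes that passed. Among 40 genes of ER targeting, translocation and the signal peptidase, SEC61B of the translocon had a log2 fold change of 2.35. Its guides differed widely (SD over guides 2.17), at 54.1 ± 5.34 against 11.6 ± 3.89 CPM. The signal peptidase subunit SPCS3 had 1.37 (SD over guides 1.18, 87.7 ± 14.3 against 32.9 ± 8.67 CPM). Adjusted over the list alone, 4 of the 40 genes were enriched, with SEC61G and SEC63 added, and SRP54 was depleted. Among 56 genes of lysosome delivery the ESCRT-II subunits VPS36 (log2 fold change 1.66, SD over guides 1.03) and SNF8 (1.68, SD 0.58) passed. Adjusted over the list alone 5 were enriched, with VPS28, CHMP4B and CHMP6 added, and ATP6V1D was depleted. CUL3 was the only passing gene of 39 in the cullin list, also adjusted over the list alone. CUL3 and CMTM6 passed among 35 reported regulators of PD-L1, and USP9X (log2 fold change 1.26) was added when adjusted over the list alone. USP9X had 0.74 without CD58-low replicate 1, and over all genes it passed without CD58-low replicate 2 and with the replicate block (adjusted p 0.0315). Of the chromatin lists, KMT2D and its complex partner, the histone demethylase KDM6A (log2 fold change 1.38), passed among 34 genes of deacetylase, CoREST and MLL complexes, with PAXIP1 added when adjusted over the list alone. ACTL6A (1.48, SD over guides 1.67) passed among 26 SWI/SNF genes and MED23 (0.84, SD 0.39) among 46 Mediator and SAGA genes. Adjusted over the list alone ARID1A was added to the former and none to the latter. FOSL1 (0.89), an AP-1 transcription factor, passed in the list of the MAPK pathway and melanocyte lineage, and JUNB (0.80) was added when adjusted over the list alone. No member passed by RRA over all genes for Golgi transport (49 genes), endosomal recycling (42), ER-associated degradation (31), MHC class I presentation (21), interferon-gamma and JAK-STAT signalling (18), NF-kappaB signalling (28), polycomb complexes (22) or the olfactory receptors (374). Adjusted over the list alone, ARCN1, COG6 and SEC23B of Golgi transport and UBE2G2 and VCP of ER-associated degradation were depleted, KDM2B of the polycomb list was enriched, and the rest of these lists had 0. These depletion calls include genes with guides without reads in CD58-low. ARCN1 had 2 of 4 such guides, at 12.04 ± 0.38 against 14.6 ± 2.07 CPM, and ATP6V1D above had 2 of 4. For such genes loss of guides cannot be told apart from an effect of the sort. Of 16 alternative settings MED23 and FOSL1 lost their calls in 6 each (log2 fold changes from 0.44 to 1.12 and from 0.57 to 1.10), ACTL6A in 4 (log2 fold change from 0.26 to 1.76), SPCS3 in 3, SEC61B and VPS36 in 2 and SNF8 in 1. Among these settings, FOSL1, ACTL6A and SPCS3 did not pass without CD58-low replicate 1, MED23 without replicate 2, ACTL6A, MED23 and FOSL1 without CD58-mid replicate 1, and MED23 and FOSL1 without CD58-mid replicate 2.

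TBC1D10B, which activates the GTPase activity of Rab proteins, was the only gene depleted in CD58-low, at 14.5 ± 3.19 CPM against 39.8 ± 0.1 CPM in CD58-mid (log2 fold change -1.30, adjusted p 0.042), and its call was lost in 9 of 16 alternative settings (log2 fold changes from -2.24 to -0.76), among them those without CD58-low replicate 1 or 2 or CD58-mid replicate 2. The next 9 genes did not pass (adjusted p 0.218 each). PRR12 guides stood at 55.4 ± 4.45 against 89.5 ± 19.5 CPM, and MPI was given above. The other 7 are needed for growth of most cells, had low abundance in both populations and had guides without reads in CD58-low, so CPM are given without fitted folds. MCM7, of the replicative helicase, had 1.63 ± 0.6 against 7.43 ± 1.45 CPM, and NCAPD2, of condensin, 7.88 ± 0.15 against 20.5 ± 3.86 CPM. MEPCE had 3.68 ± 1.16 against 10.2 ± 2.91 CPM, ATP6V1D 2.85 ± 0.7 against 11.2 ± 0.44 CPM, ARCN1 12.04 ± 0.38 against 14.6 ± 2.07 CPM, and POLR1A 2.54 ± 0.98 against 4.79 ± 0.18 CPM. For the spliceosomal gene SNRPD3 all 4 guides had 0 reads in both CD58-low libraries, which allows up to 0.118 and 0.185 CPM per guide, against 4.56 ± 1.27 CPM summed in CD58-mid.

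At the level of single guides 69 of 76005 differed, 47 higher and 22 lower in CD58-low; the deposited normalized values with limma gave 133, 29 higher and 104 lower, and the fit with the replicate number as a block gave 39. The count was 18932 without CD58-low replicate 1, 8133 without CD58-low replicate 2, 10 with either CD58-mid library left out, 2059 with the DESeq2 Wald test, 9 with only the groups compared, 14 and 16 with technical replicate A or B alone, and 129 with limma voom with group weights, chosen after seeing the data. The 60 enriched genes became 26 with technical replicate B of the sorted samples alone, 31 without CD58-low replicate 1, and 12 with fry per gene in place of RRA, while the voom fit gave 70.

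CD58-low was also set against the unsorted cells of day 10. CD58 guides were at 391 ± 17.3 CPM in CD58-low and 22.4 ± 2.84 CPM on day 10, a 17.5-fold difference (log2 fold change 4.1). DNAJC13 (3.02), PGAP2 (2.44), CUL3 (2.33), DYRK1A (1.74), CMTM6 (1.70), KMT2D (1.70), NF2 (1.66), RUNX1 (1.57) and TOX4 (1.35) were enriched here too; this comparison shares the CD58-low libraries with the preceding comparison. The GPI genes PIGV (1.75), PIGO (1.37), PIGW (1.31), PIGX (1.22) and PIGP (1.07) also passed. In total 56 genes were enriched and 2 depleted by RRA, namely MCM7, at 1.63 ± 0.6 against 8.21 ± 1.04 CPM with 3 of 4 guides without reads in both CD58-low libraries, and BRPF1, a chromatin reader, at 35.7 ± 3.59 against 55.4 ± 1.45 CPM (adjusted p 0.0459 for both). TBC1D10B did not pass here (adjusted p 0.278). With technical replicate B alone 26 genes were enriched, with fry per gene 11, and without CD58-low replicate 1 there were 23; technical replicate A alone gave 37. The 2 depleted genes became 0 without CD58-low replicate 1, 4 without CD58-low replicate 2 (neither MCM7 nor BRPF1 among them), 1 without day 10 replicate 1 and 1 with the replicate block, where MCM7 did not pass (adjusted p 0.0841); BRPF1 also did not pass without day 10 replicate 2, PIGX without CD58-low replicate 1 and PIGW without CD58-low replicate 2.

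CD58-mid, the control gate, was compared with the unsorted cells of day 10 from which it came. CD58 guides were lower, at 3.12 ± 1.79 CPM in CD58-mid against 22.4 ± 2.84 CPM (log2 fold change -2.72, adjusted p 0.00382). DNAJC13 (-0.61) and PGAP2 (-0.43) were also depleted (adjusted p 0.0051 for both). The other 3 depleted genes, named after their values were seen, were ALG5 (-0.68), which makes dolichol-phosphate glucose, the microtubule protein EML4 (-0.48) and SUPT20H (-0.40) of the SAGA complex. CMTM6, CUL3, NF2, KMT2D, the further genes of the first 15 and CD274 did not pass in this comparison. No gene was enriched by RRA (994 genes had an unadjusted p under 0.05), and 0 of 76005 single guides differed. The 6 depleted genes became 2 with the deposited normalized values and limma, 0 with fry per gene, 2 without CD58-mid replicate 1, 1 without CD58-mid replicate 2, and 3 with either day 10 library left out. CD58 lost its call in 1 of 16 alternative settings (fry per gene), DNAJC13 and PGAP2 in 7 each, and ALG5, EML4 and SUPT20H in 8 each; the replicate block ended the call of SUPT20H (adjusted p 0.0741).

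Day 10 against the virus measures the change in guide abundance during growth of the whole culture; the virus is a single library, assumed to vary like the other groups. Guides against HSPE1, a mitochondrial chaperonin, fell from 36.3 CPM in the virus to 0.91 ± 0.79 CPM on day 10 (log2 fold change -5.59). Large decreases were also measured for TUBB (-4.91), a beta-tubulin, the ribosome biogenesis factor EIF6 (-4.77), the proteasome subunit PSMA6 (-4.92), the splicing protein SNRPD1 (-4.72), the ribosomal genes RPS19 (-4.75), RPL27A (-4.74) and RPL23 (-4.71), the RPL17-C18orf32 readthrough gene (-5.35), and WASH1 (-5.36). Whether the WASH1 guides cut at several sites, or the readthrough guides cut RPL17, was not examined, so these 2 decreases do not show a need for the named gene. PDCD10 guides rose from 46.1 to 123 ± 5.69 CPM (log2 fold change 1.35), and NF2 guides from 28.1 to 71.0 ± 0.23 CPM (1.28). The Hippo pathway kinases TAOK1 (1.24), LATS2 (1.21) and MAP4K4 (0.89) rose as well, as did the semaphorin receptor gene NRP1 (1.19), the taste receptor gene TAS2R43 (0.97), PNPLA4 (0.95) and the Y-linked family members XKRY (1.00) and CDY2B (0.98). Over all genes the median was 0.24 on the X chromosome (801 genes) and 0.74 on Y (47 genes). Whether guides against Y genes had a site, or several, to cut in these cells was not examined. The rise of XKRY, CDY2B and other Y genes therefore does not show an effect of losing the named gene. In total 1050 genes were depleted and 43 enriched by RRA. At the level of single guides 0 of 76005 differed, so these calls rest on ranks combined over the guides of a gene. The deposited normalized values with limma gave 2 guides higher and 680 lower. RPS19 and MAP4K4 did not pass with either day 10 library left out, CDY2B without replicate 1 and PNPLA4 without replicate 2.

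Of 8 growth lists 7 were called in day 10 against the virus. Among 81 cytosolic ribosomal proteins 58 were depleted (74 adjusted over the list alone), with a median log2 fold change of -3.67; examples are RPL13 (-4.62), RPL6 (-4.40) and RPLP0 (-4.25). The camera adjusted p was 1.75e-67, and 0.000804 with an estimated correlation. Of 39 spliceosome genes 27 were depleted (37 adjusted over the list alone), among them PRPF19 (-3.48) and SF3B1 (-3.02), and of 39 proteasome genes 23 (31 adjusted over the list alone), among them PSMA5 (-4.31) and PSMB3 (-3.86). Of 74 mitochondrial ribosomal proteins 9 were depleted (20 adjusted over the list alone), with a list median of -0.67; MRPS12 (-1.07) and MRPL41 (-1.03) are examples. In complex I NDUFB10 (-1.08) and NDUFB7 (-0.69) of 37 genes were depleted, and adjusted over the list alone NDUFA1 as well. Of 38 tumour suppressors 6 were enriched and none was depleted: NF2, TAOK1, LATS2, RB1 (0.84), the kinase ATM (0.73) and CUL3. Adjusted over the list alone 12 of them were enriched, with the Hippo adaptor SAV1 (1.09) and AMOTL2 (0.95) among those added; the camera adjusted p was 2.59e-09, and 0.0166 with an estimated correlation. The 374 olfactory receptors, which this cell type is not known to need, had a median of 0.15 and were called as higher (camera adjusted p 0.00478). OR2T11 (0.71) was enriched, and OR4F3 (-1.31) and OR4F16 (-1.60) were depleted. Whether guides against OR4F3 and OR4F16 cut at several sites was not examined. The MAPK and melanocyte list was not called (adjusted p 0.175), but MAP2K1 (-2.22) was among its depleted genes; adjusted over the list alone BRAF (-2.0, adjusted p over all genes 0.0976), SOX10 (-1.83) and ETV4 (-0.93) were added. The 43 enriched genes became 23 with the deposited normalized values and limma, 28 with the stricter filter, 28 with technical replicate B of the sorted samples alone, 79 with fry per gene, 28 without day 10 replicate 1 and 27 without day 10 replicate 2; the 1050 depleted genes became 504 with the stricter filter, 664 when the top 10% of guides count, and 431 with fry per gene. With either day 10 library left out ATM, MAP2K1, NDUFB7 and OR4F16 did not pass, and RB1 and OR2T11 did not pass without replicate 2. With the replicate block CUL3 (adjusted p 0.0625), MAP2K1 (0.0508), OR2T11 (0.0509) and OR4F16 (0.0511) did not pass, and SAV1 did (0.0229).

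**Figure D4:**
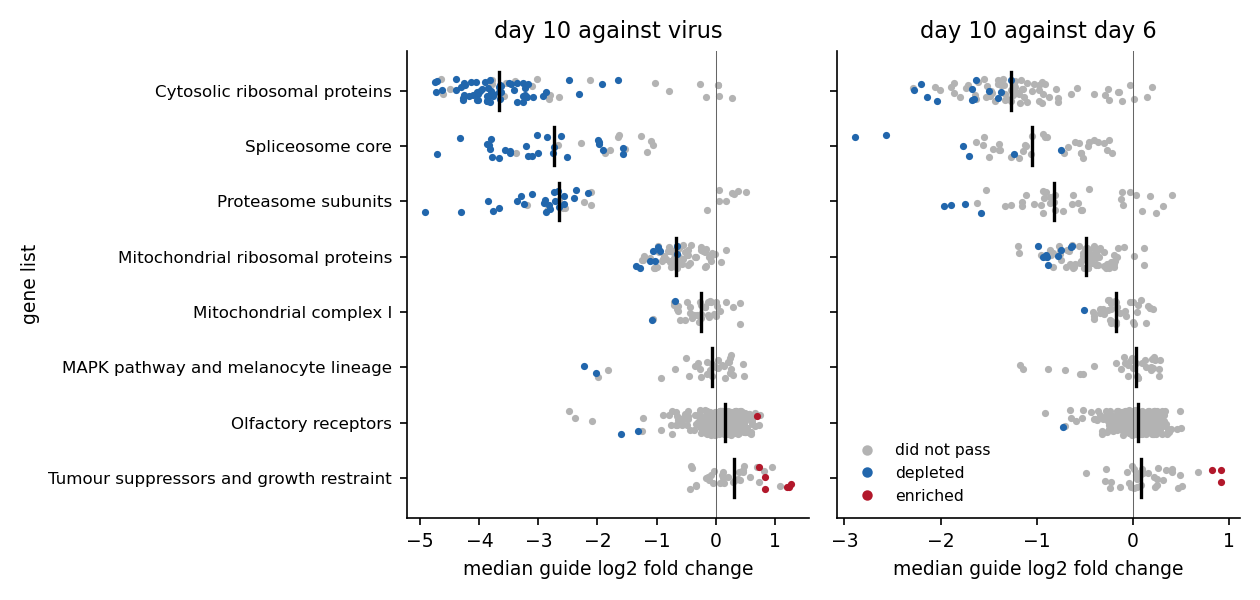
Median log2 fold change of a gene's guides (x axis) for every gene of the 8 growth lists (y axis), in day 10 against the virus and day 10 against day 6; points are genes, coloured by the gene-level call, and vertical bars are list medians. Cytosolic ribosomal proteins have a median of -3.67 against the virus and -1.27 against day 6, and tumour suppressors 0.31 and 0.08.

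By day 6 the largest decreases from the virus were those of HSPA5, the main chaperone of the ER lumen, from 104 to 9.38 ± 2.15 CPM (log2 fold change -3.66), and of RPL17, from 56.7 to 5.28 ± 0.9 CPM (-3.59). RPL17-C18orf32 (-3.25), RPL23A (-3.24) and the elongation factor EEF1A1 (-3.19) followed. The 3 enriched genes were CUL3, from 74.3 to 113 ± 10.6 CPM (0.73), XKRY (0.72) and ZNF705B (0.53). There were 273 depleted genes by RRA, while 0 of 76005 single guides differed. The block of the replicate number gave 7 enriched genes in place of 3; 51 genes were depleted with the stricter filter, 457 with the deposited normalized values and limma, 0 with fry per gene, 698 with voom, 106 without day 6 replicate 1 and 40 without day 6 replicate 2. EEF1A1 did not pass with either day 6 library left out, XKRY and ZNF705B without replicate 1, and CUL3 and RPL17-C18orf32 without replicate 2; with the replicate block EEF1A1 did not (adjusted p 0.0826).

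From day 6 to day 10, where both groups have replicates, PDCD10 guides rose from 64.2 ± 4.76 to 123 ± 5.69 CPM (log2 fold change 0.92) and NF2 guides from 40.1 ± 3.83 to 71.0 ± 0.23 CPM (0.91). TAOK1 (0.92), LATS2 (0.82) and NRP1 (0.72) also rose. Guides against HARS, the histidyl-tRNA synthetase, fell most (-3.55), followed by EIF6 (-3.53), the TFIIH helicase ERCC3 (-3.50), the clamp loader subunit RFC3 (-3.39) and UBA1 (-3.39), which activates ubiquitin. In total 702 genes were depleted and 7 enriched by RRA, while 0 of 76005 single guides differed. Of the 8 lists 6 were called: 12 of 81 cytosolic ribosomal proteins were depleted (37 adjusted over the list alone; RPLP2 -2.21, RPL27A -2.14), 6 of 39 spliceosome genes (15; SNRPD1 -2.89, DHX15 -2.57), 4 of 39 proteasome genes (13; PSMA7 -1.96, PSMA5 -1.90), and 9 of 74 mitochondrial ribosomal proteins (35; MRPL41 -0.99, MRPL44 -0.90). NDUFB10 (-0.51) was depleted among 37 complex I genes (0 adjusted over the list alone; camera adjusted p 0.0175, fry adjusted p 0.082). LATS2, NF2 and TAOK1 were enriched among 38 tumour suppressors (11 adjusted over the list alone, SAV1 at 0.67 among them), and all 6 calls hold with an estimated correlation. The olfactory receptors were not called (adjusted p 0.0796) but were with an estimated correlation (adjusted p 0.0135), and OR4F3 (-0.73) of them was depleted. With fry per gene 20 genes were depleted and 0 enriched, and the stricter filter gave 459 depleted genes; there were 426 without day 10 replicate 1 and 433 without day 10 replicate 2. NDUFB10 lost its call in 10 of 16 alternative settings, among them those with any 1 of the 4 libraries left out. PSMA5, PSMA7, RPL27A, MRPL41, OR4F3 and PDCD10 did not pass without day 10 replicate 1, nor PSMA5, RPL27A and DHX15 without day 10 replicate 2. Neither did PSMA5, RPL27A, RPLP2 and SNRPD1 without day 6 replicate 1, and PSMA7 and MRPL44 without day 6 replicate 2. With the replicate block PSMA7 did not pass (adjusted p 0.0826).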

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

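The voom fit with group weights, and the mean in place of the planned sum over columns of the deposited normalized values, were chosen after seeing the data; all other settings were fixed before. For 180 combinations of a gene and a comparison, which include all those with values in the text, 2252 of 2666 values kept their direction and their side of the threshold, 372 kept the direction but no longer passed, 42 newly passed, and 0 changed direction. CD58, DNAJC13, PGAP2, DYRK1A, PIGO and KDM6A passed in CD58-low against CD58-mid in all 16 settings, and CMTM6 in 15, with log2 fold changes from 1.71 to 2.26. For 114 of the 372 the setting was fry per gene. Fry per gene and the top 10% of guides in RRA use the folds of the main fit, so their 180 values each could not change direction. Many of the genes were also chosen for the same sign in both replicates, so the 0 that changed direction is weak evidence of stability. DESeq2 size factors and no filter moved no call of these genes, and no count of genes or guides by more than 1.5 times. Scaling and a null from non-targeting guides were not run, since the tables name none; the stricter filter left genes with too few guides without a value. Except where said, the cause was not tested.

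With the DESeq2 Wald test CD58-low against CD58-mid had 0 depleted genes and 2059 guides. With the deposited normalized values and limma it had 3 depleted genes and 133 guides (29 higher, 104 lower; 47 and 22 in the edgeR fit); depleted genes were 2 in CD58-mid against day 10 and 457 in day 6 against the virus, and enriched genes 23 in day 10 against the virus. With only the groups compared, which leaves fewer samples, CD58-low against CD58-mid had 0 depleted genes and 9 guides. With the replicate block it had 39 guides; CD58-low against day 10 had 1 depleted gene and day 6 against the virus 7 enriched genes. Of the 180 combinations the block ended 12 calls and added 3, and it changed no call of a list. The stricter filter, which leaves fewer guides, gave 1 depleted gene in CD58-low against day 10, 28 enriched and 504 depleted in day 10 against the virus, 51 depleted in day 6 against the virus and 459 depleted in day 10 against day 6.

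Technical replicate A alone, with fewer reads, gave 0 depleted genes and 14 guides in CD58-low against CD58-mid, 37 enriched and 0 depleted in CD58-low against day 10, and 11 enriched in day 10 against day 6. Technical replicate B alone gave 26 enriched and 0 depleted genes and 16 guides in CD58-low against CD58-mid, 26 enriched and 0 depleted in CD58-low against day 10, 28 enriched in day 10 against the virus and 6 enriched in day 6 against the virus. Voom with group weights gave 0 depleted genes and 129 guides in CD58-low against CD58-mid, 8 depleted in CD58-low against day 10 and 698 depleted in day 6 against the virus. With the top 10% of guides in RRA, 664 genes were depleted in day 10 against the virus.

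Fry per gene gave 12 enriched and 3 depleted genes in CD58-low against CD58-mid, 11 and 4 in CD58-low against day 10, 0 depleted in CD58-mid against day 10, 79 enriched and 431 depleted in day 10 against the virus, 0 and 0 in day 6 against the virus, and 0 and 20 in day 10 against day 6. Fry over lists called 4 lists in CD58-low against CD58-mid in place of 2, with the CMTM family (adjusted p 0.0311) and Mediator and SAGA (adjusted p 0.00723, lower) added.

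Leaving out each library in turn, where the lone sample is assumed to vary like the other groups, gave these ranges. CD58-low against CD58-mid had 31 to 51 enriched and 0 to 2 depleted genes and 10 to 18932 guides; the highest guide counts arose without a CD58-low library, when the spread within that group no longer enters the estimate. CD58-low against day 10 had 23 to 53 enriched and 0 to 4 depleted genes, CD58-mid against day 10 1 to 3 depleted, day 10 against the virus 27 to 28 enriched, day 6 against the virus 40 to 106 depleted, and day 10 against day 6 426 to 503 depleted. Depth sets what 0 reads allow, up to 0.118 and 0.185 CPM in CD58-low, where 2.52% and 5.02% of guides had none.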

Other observations

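The gene groups and the overlap below, the tests of the GPI steps and the test of read depth behind the guides without reads were chosen only after the result was seen; the other tests were written before. Among the 60 genes enriched in CD58-low against CD58-mid, several outside the fixed lists are known partners of each other or of a gene named above. The phosphoinositide phosphatase MTMR6 and its inactive partner MTMR9 had log2 fold changes of 1.24 (SD over guides 0.16) and 1.30 (0.27), with an adjusted p of 0.000191 for both. KCTD10, a substrate adaptor of CUL3, had 1.41 (0.36), and CBFB, which binds DNA together with RUNX1, had 1.80 (0.55). The exocyst subunits EXOC5 and EXOC7 had 1.68 (0.71) and 1.16 (0.31), and the tRNA deaminase subunits ADAT2 and ADAT3 had 1.05 (0.59) and 0.85 (0.42). In the ER, the transporter ATP13A1 had 2.08 (0.52), TMEM208 had 1.51 (0.47) and the chaperone HSPA13 had 1.09 (0.31). Of 16 alternative settings EXOC5 lost its call in 7, ADAT3 in 6, EXOC7, ADAT2 and MTMR6 in 4, HSPA13 and TMEM208 in 3, MTMR9, KCTD10 and CBFB in 2 and ATP13A1 in 1. With the replicate block ADAT3 did not pass (adjusted p 0.0531), and its log2 fold change ran from 0.51 to 1.10 over the settings. Without CD58-low replicate 1 EXOC5, EXOC7, ADAT3, MTMR6, MTMR9, KCTD10, HSPA13 and TMEM208 did not pass, without replicate 2 EXOC5 and ADAT2, without CD58-mid replicate 1 EXOC5 and ADAT3, and without CD58-mid replicate 2 EXOC7. No enrichment test was made of these groups.

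The sort and the change from day 6 to day 10 use no library in common, although the cultures are shared. Both were tested from the same fit and share its estimates of spread, so their calls are not strictly independent, as Fisher's test assumes. Of the 60 genes enriched in CD58-low against CD58-mid, NF2 and TAOK1 were also enriched from day 6 to day 10, where 0.02 such genes would be expected if the calls were independent (two-sided Fisher's exact p 0.0002). That p was under 0.05 in 19 of 20 alternative settings (all but fry per gene), and 0.011 without CD58-low replicate 1, where 1 gene was shared. The 6 genes ACTL6A, ADAT2, ADAT3, ITPK1, METTL14 and SNF8 were enriched in CD58-low and depleted from day 6 to day 10, with 2.2 expected (Fisher's exact p 0.022). This overlap rests on calls that were often lost: the p was under 0.05 in 12 of 20 alternative settings, and with CD58-low replicate 1 or CD58-mid replicate 1 left out there were 3 shared genes (p 0.1 and 0.21). With the replicate number as a block 4 genes were shared (p 0.17), without ADAT2, ADAT3 and METTL14 and with EXOC3 added. With only the groups compared, each comparison had its own fit. There 6 genes were enriched in the sort and depleted from day 6 to day 10, with 3.2 expected (Fisher's exact p 0.13). NF2 and TAOK1 were still shared in that setting (Fisher's exact p 0.00031). In the sort METTL14 lost its call in 8 of 16 settings, ADAT3 in 6, ACTL6A and ADAT2 in 4, ITPK1 in 3 and SNF8 in 1.

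The CD58-low libraries had more guides without reads, 1929 and 3836, than any other. Fewer reads do not account for it: in replicate 1 CD58-mid, with fewer reads than CD58-low and so not thinned, had fewer such guides by a factor of 4.59 (420), and in replicate 2 CD58-mid thinned to the reads of CD58-low had fewer by a factor of 7.57 (507). For chance loss at or after the split into technical libraries, such as few cells or genomes per library, the overlap of A and B stayed within the bound set beforehand. The test used the 73957 guides with at least 10 reads in both day 10 libraries. In replicate 1, 684 of them were without reads in both A and B, 1.32 times the 517.8 expected from independence within abundance bins. In replicate 2 there were 2213, 1.1 times the 2011.6 expected. Both counts exceed independence, so the bound does not show that all loss came after the split, and some loss shared by A and B stays possible. Rarer guides, with most of the zeros of replicate 1, were not part of this test. Removal of knockouts by the gate stays open: among the same guides, genes with 2 or more at 0 were 1.6 times as many as in random placement in replicate 1 (46 against 28.8), between the bounds set for it, and 1.2 times in replicate 2 (217 against 181.1), under the lower bound, while both counts exceed the highest of 1000 random placements (44 and 211). For this reason the genes of low abundance that ranked next in the depleted direction are given as CPM only.

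Of 17 genes of GPI synthesis 12 passed as enriched in CD58-low and none of the 5 transamidase subunits did. The mean log2 fold changes were 1.24 (SD 0.56) and 0.08 (SD 0.27). Every synthesis gene but PIGZ (-0.04) had a value above 0, and the transamidase genes lay between -0.27 and 0.39. The simulated sort recovered 18% of genes raised 2-fold, so a small rise of the transamidase genes could have been missed. Of the 5 genes that act after attachment, with a mean of 0.76 (SD 1.24), PGAP2 (2.91) was the highest of all 32 and PGAP3 had 0.71. The tables argue against transamidase guides too rare to show a rise, since 4 of the 5 genes were at or above 25.1 CPM in CD58-mid, the lowest value among synthesis genes that passed. Guides that do not cut are not excluded. The 5 genes had a median log2 fold change of -0.31 in day 10 against the virus, as low as only 0.41% of 10000 random sets of 5 olfactory receptor genes. These sets were not matched on chromosome: 162 of the 374 receptors lie on chromosome 11, where their median was 0.192, against -0.011 on chromosome 1. A median of 5 genes also does not show that the guides of each gene cut. Chance order stays open: the 2 steps were picked after their values were seen, so the exact one-sided permutation p of 0.00038 over 26334 splits does not exclude it. No biological explanation was tested, because the design has no group that separates the steps.

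Between the virus and day 10 the median log2 fold change differed by chromosome, at 0.24 for the 801 genes of X and 0.74 for the 47 genes of Y, of which 9 were enriched. Low starting abundance does not account for the rise of X and Y: both medians lay at percentile 100.0 of 10000 random gene sets matched on abundance in the virus. Other chromosomes also lay at the ends, among them 18 (median 0.18, percentile 100.0) and 1 (median -0.11, percentile 0.0). Whether guides against Y genes had a site to cut in these cells was not examined, so their rise may have another source than the other chromosomes. An effect of the locus whatever the gene, such as the number of cuts set by copy number, may contribute, since neighbouring genes that did not pass had correlated changes after chromosome medians were taken off (lag-1 rank correlation 0.206 across 17841 neighbouring pairs of genes, which are not independent replicates, permutation p 1e-05, the smallest possible). Without neighbours that share the first 3 letters of their symbols the correlation was 0.178, and across 11 chromosomes the median of olfactory receptors rose with that of the other genes (rho 0.63, permutation p 0.022). X and Y, with 1 and 0 olfactory receptor genes, were not among these 11. No copy numbers came with the tables, so no biological explanation was tested.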
